A study of Homo sapiens with 4 samples.

How the data were processed

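RNA-seq libraries of MDA-MB-453 breast cancer cells were compared, 2 from wild-type cells and 2 from cells labelled as TMEM9 KD. How TMEM9 was reduced is not given in the sources used here. Per the labels' protocols, RNA was extracted with a silica column kit that removes genomic DNA, and libraries were made from 1 ug of total RNA by a standard Illumina protocol. The authors deposited a table of raw counts per gene, with 48162 Ensembl genes and a column per library. The submitters' processing notes name CASAVA, Bowtie 0.12.2 and the builds hg19 and mm8, without their roles. The counting tool, the gene annotation and the strand setting are not given in the sources used here. As the reference annotation used here is of another build, no coordinates are given, and GENCODE 29 served only for names, gene types, lengths, GC content and the chromosome and order of genes. The series text describes the profiles as retinal, which goes against the cell line in every label, so a list of photoreceptor genes was included.

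Symbols were found for 45336 genes, of which 298 came from GENCODE 29, and 2826 had none, holding at most 0.64% of the counts of a library. No count was found in any library for 18749 genes. Every column of the table belonged to a sample. Totals per library ran from 15323843 to 18517337 counts.

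The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM factors, filterByExpr defaults (minimum count 10, minimum total 15) and group as the only term. P-values were adjusted by Benjamini-Hochberg over the 14923 genes tested, with a threshold of 0.05. The model had 2 residual degrees of freedom per gene, and the common biological coefficient of variation was 0.0498. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members, adjusted over the lists, and again with an estimated correlation. The 36 lists were written before the data were examined and cover lysosomes and v-ATPase, Wnt, inflammation, lineage markers, growth, stress, metabolism, RNA quality and other cell types. Of 1069 list entries, 1047 matched a gene, and 35 lists could be tested. With an estimated correlation, camera takes its p-value on the 2 residual degrees of freedom. It has little power on so few, so failing it does not decide against a list. For ER chaperone genes the estimated correlation was 0.00975, near the preset, yet the unadjusted camera p went from 1.06e-05 to 0.0476. The estimated correlation was also near or below the preset for histone genes (0.00798) and p53 targets (-0.0264). For other called lists it was higher, such as 0.803 for mitochondrially encoded transcripts, 0.221 for NRF2 targets and 0.116 for MYC targets. Where the genes of a list are that correlated, the preset p may be too small.

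The genes named in the text follow a rule fixed before the data were examined. It takes TMEM9, then the 12 largest increases and 12 largest decreases in fitted log2 fold change. These need an adjusted p below 0.05, a mean of at least 5 CPM, a symbol, and both knockdown libraries on the same side of both wild-type libraries. From each list it takes up to 4 members past the threshold with the largest absolute change. The text gives only some of the genes that this rule names. Where a group had 0 counts, a lower bound was computed against a floor of 3 counts over the group, and with 1 to 3 counts a ratio was given with its exact Clopper-Pearson 95% interval.

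The libraries of a group were compared before they were averaged. Over genes with at least 20 counts in a pair, chi-square over degrees of freedom was 2.04 for the WT pair and 4.83 for the TMEM9 KD pair, against 68.5 and 80.5 for same-numbered libraries across groups. Both pairs differed by more than sampling noise, and each library was kept as a replicate. This spread may be technical and does not show that the libraries of a group came from separate cultures. A principal component with 90.2% of the variance separated the groups.

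The edgeR fit and list test were tested on simulated counts for this comparison, with 14634 genes fitted and 50 genes changed at each fold. They called 44% of genes changed 1.25-fold, 84% at 1.5-fold, 90% at 2-fold and 98% at 4-fold. Of 14404 unchanged genes, 9 were called, which was 5.08% of the calls. Of the lists left unshifted, 0 were called. The simulated genes were drawn independently and most were unchanged, while in the data 57.7% of the genes were called. The simulation thus cannot tell how often lists of correlated genes are called wrongly.

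Alternatives were other scaling (DESeq2 size factors, upper quartile, library size only), filters (none, or a mean of at least 5 CPM), tests (DESeq2 1.42.0, limma voom, a test against 1.5-fold), fry, leaving out the 20 most abundant genes, a replicate block, and leaving out each library. After DESeq2 and after the test against 1.5-fold, lists were tested with cameraPR of limma on the gene statistics, with the preset correlation. These list tests thus differ from the main one in more than the gene fit. A list given as tested against 1.5-fold was still compared with the other genes, not with a 1.5-fold change. Removal of a trend on GC content and length, and of each autosome's median, was added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.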

Results

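RNA from MDA-MB-453 cells, a human breast cancer line that carries the androgen receptor, was sequenced from 2 groups of 2 libraries. One group was wild type (WT) and the other had reduced TMEM9 (TMEM9 KD). TMEM9 encodes a membrane protein of lysosomes and endosomes that binds the proton pump of these organelles. The wild-type libraries held 15323843 and 18517337 counts in genes, and the knockdown libraries 15960941 and 17065126. Mitochondrially encoded transcripts took 3.98% of the counts in both wild-type libraries, and 3.18% and 2.83% in the knockdown libraries. Values below are CPM, counts scaled to the library total with TMM factors, as mean ± SD with n = 2 per group. Log2 fold changes are of TMEM9 KD against WT. Their SE was back-calculated as the absolute log2 fold change over the square root of its F statistic. No label says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

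The comparison asks how the transcriptome of these cells differs when TMEM9 is reduced. TMEM9 (ENSG00000116857) fell from 79.1 ± 5.92 CPM in WT to 3.79 ± 0.957 CPM in TMEM9 KD. Its log2 fold change was -4.37 (SE 0.126, edgeR quasi-likelihood adjusted p = 4.12e-52), with 1120 and 1497 counts in WT against 51 and 78 in TMEM9 KD. Of 14923 genes tested, 4283 were higher and 4335 lower in TMEM9 KD, which is 57.7% of the genes. Of these, 1081 were higher and 1512 lower by at least 2-fold, and 338 and 663 by at least 4-fold. The groups did not overlap in 77.6% of the genes, where chance gives 33.3%. Tested against a change of 1.5-fold, 1111 genes were higher and 1692 lower. Among genes with a mean of at least 5 CPM, 387 were higher and 713 lower by at least 2-fold.

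The largest increases named by the fixed rule were led by MAGEB2, a cancer-testis antigen, with 43.1 ± 2.36 CPM in TMEM9 KD and a single count over both WT libraries. The ratio for MAGEB2 was 1420 (95% counting interval 255 to 56100). GFRA1, a co-receptor for glial cell line-derived neurotrophic factor, rose from 0.446 ± 0.316 to 53.3 ± 1.1 CPM (log2 fold change 6.94, SE 0.203). ANXA3 rose from 0.234 ± 0.141 to 26.4 ± 0.608 CPM, and GPNMB, a glycoprotein of lysosomes and melanosomes, from 2.11 ± 0.241 to 47.1 ± 1.21 CPM. THBS2, a matrix glycoprotein, rose from 4.55 ± 0.569 to 69.5 ± 1.89 CPM. The other genes of this set were NTF3, SEMA3E, CPA3, PPP4R3C, LINC00665, CACNA2D1 and NTNG1, with log2 fold changes between 4.11 and 6.23. MAGEB2 belongs to a family of genes that share sequence, among which some reads may have been split.

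Among the largest decreases, GJB2, MIR205HG, KRT14 and SERPINB3 had no counts in either knockdown library. Against a floor of 3 counts over the group, GJB2, a gap junction protein, was at least 301-fold lower from 26.6 ± 1.27 CPM in WT. MIR205HG was at least 302-fold lower, the basal keratin KRT14 at least 168-fold, and SERPINB3, which shares sequence with SERPINB4, at least 116-fold. The growth factor gene CSF3 fell from 79.4 ± 1.98 to 0.237 ± 0.0107 CPM (log2 fold change -8.35, SE 0.196). CYBA, a subunit of NADPH oxidase, fell from 44.8 ± 0.201 to 0.149 ± 0.0485 CPM, and the chemokine gene CXCL11 from 52.4 ± 1.44 to 0.21 ± 0.135 CPM. SHISA2 fell from 27.7 ± 3.62 to 0.118 ± 0.00536 CPM. Ratios of WT to TMEM9 KD were 529 for MID1IP1 (95% counting interval 94.5 to 20900), 383 for CXCL10 (131 to 1860), 276 for AOC1 (76 to 2280) and 161 for TP73 (54.9 to 785). These floors and intervals cover counting error only.

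**Figure D1:**
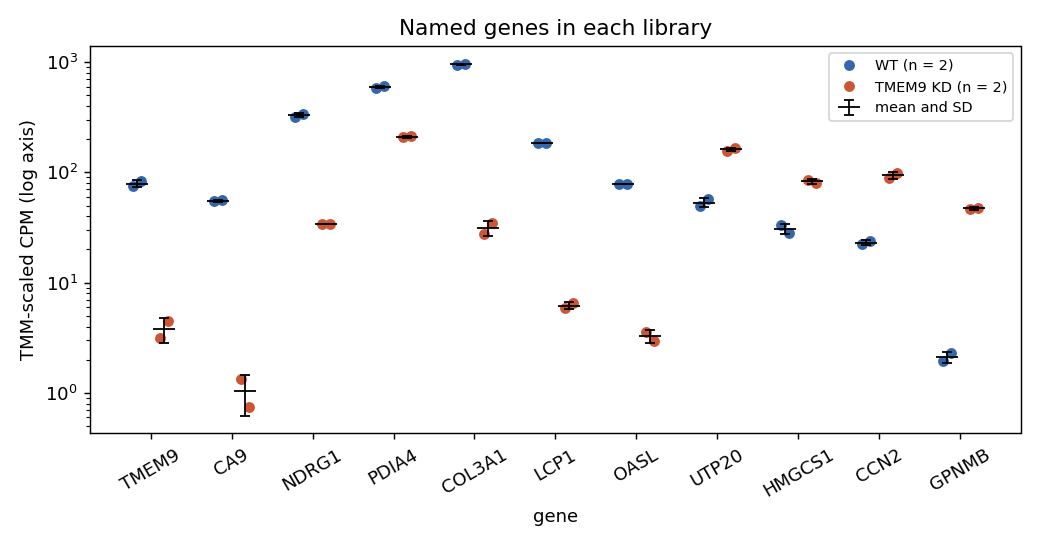
TMM-scaled CPM on a log axis for 11 genes in each library, with points for the libraries (n = 2 per group) and a bar for the mean and SD. TMEM9 lies near 79.1 CPM in WT and 3.79 in TMEM9 KD, and in each gene shown the libraries of a group lie closer to each other than to the other group.

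Genes of hypoxia and glycolysis were lower in TMEM9 KD. Of 34 members tested, 32 fell and 0 rose, with a median log2 fold change of -0.82 (camera adjusted p = 3.14e-10 with a preset correlation, adjusted p = 0.376 with an estimated correlation). CA9, a carbonic anhydrase induced by low oxygen, fell from 55.2 ± 0.998 to 1.04 ± 0.424 CPM. EGLN3, an oxygen sensor, fell from 81.4 ± 2.4 to 5.76 ± 1.41 CPM, NDRG1 from 330 ± 14.1 to 34 ± 0.201 CPM, and the glycolytic enzyme gene ALDOC from 12.7 ± 1.01 to 3.28 ± 0.228 CPM. Genes of ER chaperones and the unfolded protein response were also lower, with 21 of 27 past the threshold downward and 0 upward (median -0.44; adjusted p = 6.19e-05 preset, adjusted p = 0.376 with an estimated correlation). PDIA4, a disulfide isomerase, fell from 594 ± 15 to 210 ± 3.63 CPM, and EDEM1, which acts in ER-associated degradation, from 240 ± 7.07 to 127 ± 12.6 CPM. DNAJC3, a co-chaperone, fell from 146.9 ± 2.89 to 64.2 ± 6.08 CPM, and DERL2 fell by 0.64 on the log2 scale. With gene statistics of the test against 1.5-fold, the ER list was not called (cameraPR adjusted p = 0.295).

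Inflammatory and interferon genes were lower. Among genes of NF-kB signalling and cytokines, 18 of 23 fell and 2 rose (median -1.16; camera adjusted p = 7.02e-06 preset, adjusted p = 0.376 with an estimated correlation). The cytokine gene IL1A fell from 113.7 ± 0.133 to 10.3 ± 0.00692 CPM and CXCL3 from 147.3 ± 7.88 to 20.2 ± 1.2 CPM, with CXCL3 sharing sequence with CXCL1 and CXCL2. Of 34 interferon-stimulated genes, 26 fell and 2 rose, or 26 and 3 adjusted over the list alone (median -1.27; adjusted p = 5.04e-07 preset, adjusted p = 0.376 with an estimated correlation). OASL, an antiviral protein, fell from 78.5 ± 0.203 to 3.29 ± 0.442 CPM and IFIT2 from 27.5 ± 1.63 to 2.04 ± 0.117 CPM. RSAD2 was at least 44.2-fold lower, with 0 counts in TMEM9 KD. Of 18 leukocyte markers matched, only 6 passed the expression filter, of which 5 fell and 1 rose (median -2.07). The list was not called (camera adjusted p = 0.0759, adjusted p = 0.463 with an estimated correlation). It was called under several alternatives, such as cameraPR on DESeq2 statistics (adjusted p = 3.4e-05) and camera with limma voom (0.00883). LCP1, an actin-bundling protein on chromosome 13, fell from 184.7 ± 1.61 to 6.2 ± 0.472 CPM. In WT, LCP1 held most of the 205.3 CPM of the tested members. PTPRC, also a leukocyte gene, went the other way, from 2.53 ± 0.359 to 4.2 ± 0.274 CPM. CD74 had a WT to TMEM9 KD ratio of 38 (95% counting interval 12.7 to 187).

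Markers of basal and myoepithelial cells were lower, with 14 of 19 falling and 3 rising, or 14 and 4 adjusted over the list alone (median -1.15; camera adjusted p = 0.000876 preset, adjusted p = 0.376 with an estimated correlation). ITGB4, an integrin of hemidesmosomes, fell from 101.8 ± 0.426 to 2.62 ± 0.62 CPM. KRT5 was at least 10.3-fold lower, with 0 counts in TMEM9 KD, and KRT6A had a ratio of 102 (95% counting interval 27.8 to 846). Of 24 luminal markers matched, only 11 passed the expression filter. These were not called, with 5 of 11 rising and 3 falling (camera adjusted p = 0.687, adjusted p = 0.886 with an estimated correlation). They had a median of 0.45 and a mean of -0.05. The luminal median was 0.149 and 0.228 without WT replicate 1 and 2, and 0.224 and 0.148 without TMEM9_KD replicate 1 and 2. ELF3 fell by 2.93 on the log2 scale, from 3.42 ± 0.114 to 0.441 ± 0.105 CPM. FOXA1, a pioneer transcription factor, rose by 1.48, from 2.83 ± 0.153 to 7.88 ± 0.521 CPM. Of 35 genes of the androgen receptor and apocrine cells matched, only 17 passed the filter. They went both ways, with 5 of 17 higher and 10 lower (camera adjusted p = 0.443, adjusted p = 0.576 with an estimated correlation). TMPRSS2 fell by 3.53 on the log2 scale, from 4.52 ± 0.415 to 0.38 ± 0.192 CPM. DHRS2 rose by 3.08, from 1.48 ± 0.108 to 12.6 ± 2.56 CPM.

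Of 29 genes of epithelial-mesenchymal transition, 12 rose and 13 fell (camera adjusted p = 0.66, adjusted p = 0.886 with an estimated correlation). COL3A1, a fibrillar collagen, fell from 957 ± 13.3 to 31.1 ± 4.78 CPM and MMP14, a membrane metalloproteinase, from 211.5 ± 2.17 to 2.48 ± 0.139 CPM, while the receptor kinase AXL rose from 228.5 ± 8.64 to 730.5 ± 19.1 CPM. Of 13 fibroblast markers, 5 rose and 8 fell (adjusted p = 0.185, adjusted p = 0.576 with an estimated correlation). The fibroblast list was called lower by cameraPR on gene statistics of DESeq2 (adjusted p = 4.69e-07) and of the test against 1.5-fold (5.53e-05). Camera called it lower with limma voom (adjusted p = 0.00492) and without a filter (0.0295). THY1 fell by 3.21 on the log2 scale and COL6A2 by 1.55. LUM had a TMEM9 KD to WT ratio of 23.8 (95% counting interval 6.26 to 202). Of 19 photoreceptor and retinal genes matched, only 6 passed the filter. Of these 6, 0 rose and 2, OPN1SW and ABCA4, fell (camera adjusted p = 0.399, adjusted p = 0.576 with an estimated correlation). The call of ABCA4 ended under DESeq2 (adjusted p = 0.0516), without WT replicate 1 (0.101) and without TMEM9_KD replicate 2 (0.0987). Endothelial markers were not tested, as 2 of the 9 matched to the table passed the expression filter.

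Several lists of growth genes were higher in TMEM9 KD. Of 30 MYC targets in ribosome biogenesis, 29 rose and 0 fell (median 0.69; camera adjusted p = 7.69e-09 preset, adjusted p = 0.376 with an estimated correlation). UTP20, a component of the small-subunit processome, rose from 53.2 ± 5.07 to 161.4 ± 5.16 CPM, and RRP9, LYAR and RRP12 rose by log2 fold changes of 1.28, 1.22 and 1.22. Of 43 genes of G1/S and DNA replication, 26 rose and 4 fell (median 0.22; adjusted p = 0.00398 preset, adjusted p = 0.388 with an estimated correlation). UNG, a uracil glycosylase, rose by 1.00 and the transcription factor gene E2F1 by 0.89. Replication-dependent histone genes rose in 10 of 15 and fell in 0, or 11 and 0 adjusted over the list alone (median 1.01; adjusted p = 0.00318 preset, adjusted p = 0.376 with an estimated correlation), led by H2BC11 from 1.06 ± 0.00928 to 5.8 ± 1.28 CPM. Histone genes are near-identical copies, so their reads may be split, and with the trend on GC content and length removed the median was 0.90 and the adjusted p 0.056. G1/S genes were not called against 1.5-fold (adjusted p = 0.285).

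Genes of cholesterol biosynthesis rose in 21 of 26 and fell in 2, or 22 and 2 adjusted over the list alone (median 0.64; camera adjusted p = 7.02e-06 preset, adjusted p = 0.376 with an estimated correlation). HMGCS1, an enzyme of the mevalonate pathway, rose from 30.6 ± 3.29 to 82.7 ± 4.45 CPM. Of 25 targets of YAP and TAZ, 18 rose and 4 fell (median 0.53; adjusted p = 0.000876 preset, adjusted p = 0.454 with an estimated correlation). CCN2, a matricellular protein, rose from 23 ± 1.13 to 94.1 ± 6.74 CPM and DLC1 from 31.6 ± 0.412 to 114.5 ± 2.04 CPM, while IGFBP3 fell from 64.6 ± 1.05 to 10.9 ± 0.512 CPM. Fatty acid synthesis genes rose in 8 of 18 and fell in 8 (adjusted p = 0.841, adjusted p = 0.896 with an estimated correlation), with a median of 0.16 and a mean of -0.07, and GPAM fell by 1.24 and FADS1 rose by 0.80 on the log2 scale.

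**Figure D2:**
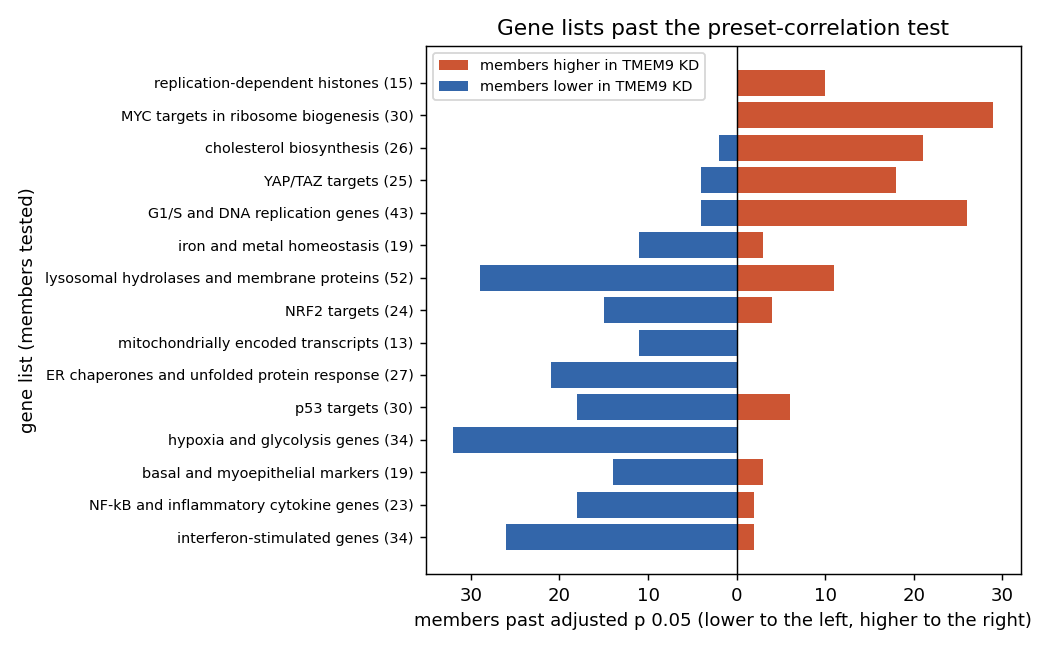
Bars give the number of members past edgeR adjusted p 0.05 that were higher (right) or lower (left) in TMEM9 KD, for the 15 gene lists past the camera test with a preset correlation, with the number of members tested in brackets. Hypoxia and glycolysis genes show 32 lower of 34, and MYC targets in ribosome biogenesis 29 higher of 30. No list passed the test with an estimated correlation, which has little power on 2 residual degrees of freedom.

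Genes of the lysosome, where TMEM9 resides, were lower in 29 of 52 members and higher in 11 (median -0.27; camera adjusted p = 0.014 preset, adjusted p = 0.545 with an estimated correlation). The protease gene CTSH fell by 2.71 on the log2 scale and the fucosidase gene FUCA1 by 2.56, while GALC, a galactosylceramidase, rose from 13 ± 1.09 to 79 ± 0.0648 CPM. Subunits of the v-ATPase were not called, with 2 of 19 higher and 5 lower (adjusted p = 0.185, adjusted p = 0.518 with an estimated correlation). ATP6V0E2 fell from 14.9 ± 1.85 to 2.81 ± 0.169 CPM and TCIRG1 from 72.3 ± 2.34 to 45.5 ± 0.284 CPM, and ATP6V0A2 rose from 28.1 ± 2.31 to 42.4 ± 2.18 CPM. Autophagy genes rose in 10 of 40 and fell in 13 (adjusted p = 0.399, adjusted p = 0.576 with an estimated correlation), among them TFEB, a regulator of lysosomal genes, which fell by 1.13. Of 7 chloride transporters of endosomes and TMEM9 relatives, 3 rose and 0 fell (adjusted p = 0.399, adjusted p = 0.692 with an estimated correlation), namely CLCN4, CLCN7 and CLCN3. CLCN3, on chromosome 4, had a log2 fold change of 0.22 and turned to -0.0377 with chromosome medians removed, and its call ended without WT replicate 1 (adjusted p = 0.161) and without WT replicate 2 (0.0696). Wnt and beta-catenin targets rose in 11 of 24 and fell in 7, or 12 and 7 adjusted over the list alone (adjusted p = 0.366, adjusted p = 0.692 with an estimated correlation), with SOX9 rising from 13.8 ± 0.438 to 62.3 ± 0.436 CPM. The lysosomal list was not called against 1.5-fold (adjusted p = 0.132).

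Targets of p53 fell in 18 of 30 and rose in 6, or 18 and 7 adjusted over the list alone (median -0.51; camera adjusted p = 0.0164 preset, adjusted p = 0.376 with an estimated correlation). BTG2, an antiproliferative gene, fell by 2.71 on the log2 scale and PMAIP1, a BH3-only protein, by 2.33. Targets of NRF2 fell in 15 of 24 and rose in 4 (median -0.28; adjusted p = 0.0204 preset, adjusted p = 0.576 with an estimated correlation), led by the near-identical reductase genes AKR1C1 and AKR1C2 which fell by 2.13 and 1.95 on the log2 scale. The NRF2 call ended without TMEM9_KD replicate 1 (adjusted p = 0.0513). Genes of iron and metal homeostasis fell in 11 of 19 and rose in 3 (median -0.28; adjusted p = 0.0439 preset, adjusted p = 0.463 with an estimated correlation). CP, ceruloplasmin, fell from 16.9 ± 1.42 to 0.355 ± 0.0161 CPM. The iron call ended in each fit that left out a library, with adjusted p = 0.0622 and 0.0779 without WT replicate 1 and 2, and 0.0562 and 0.0681 without TMEM9_KD replicate 1 and 2.

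Mitochondrially encoded transcripts fell in 11 of 13 and rose in 0 (median -0.43; camera adjusted p = 0.00936 preset, adjusted p = 0.576 with an estimated correlation). MT-CYB, a complex III subunit, fell from 2285 ± 29 to 1343 ± 89.3 CPM and MT-CO2 from 4538 ± 12.2 to 2942 ± 272 CPM. The estimated correlation of this list was 0.803, far above the preset of 0.01. The call ended against 1.5-fold (adjusted p = 0.671) and with fry (adjusted p = 0.0515). It also ended with the 20 most abundant genes left out (median -0.29, adjusted p = 0.139), which took members such as MT-CO1 out of the list. Nuclear-encoded genes of oxidative phosphorylation rose in 9 of 73 and fell in 20, or 6 and 20 adjusted over the list alone (adjusted p = 0.437, adjusted p = 0.576 with an estimated correlation), and ATP5MG fell by 0.85 on the log2 scale. Cytosolic ribosomal protein genes rose in 10 of 76 and fell in 29, or 9 and 26 adjusted over the list alone (adjusted p = 0.185, adjusted p = 0.576 with an estimated correlation). RPL21, which has many pseudogenes, fell by 0.79 on the log2 scale.

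The remaining lists were not called by the main test, and several of them were called under some alternatives. With fry, heat shock (adjusted p = 0.0274), immediate early (0.0304), HER2 and HER3 (0.00747) and snoRNA host genes (0.00747) passed the threshold, and G2/M genes (0.0834) did not. Genes of G2/M and mitosis rose in 20 of 42 and fell in 8 (camera adjusted p = 0.0835, adjusted p = 0.576 with an estimated correlation), with the anaphase activator gene CDC20 rising by 0.68. Heat shock genes rose in 12 of 19 and fell in 2 (adjusted p = 0.0634, adjusted p = 0.576 with an estimated correlation), led by HSPA1A, a near copy of HSPA1B. Immediate early genes rose in 16 of 27 and fell in 9 (adjusted p = 0.192, adjusted p = 0.576 with an estimated correlation), with FOSL1 rising from 61 ± 2.81 to 219.3 ± 12.9 CPM. Genes of HER2 and HER3 signalling rose in 4 of 33 and fell in 15 (adjusted p = 0.144, adjusted p = 0.463 with an estimated correlation), and the ligand gene TGFA fell from 67.9 ± 3.98 to 3.33 ± 0.903 CPM. Apoptosis regulators rose in 10 of 29 and fell in 14 (adjusted p = 0.462, adjusted p = 0.692 with an estimated correlation), with BIRC3 rising by 1.61. ATF4 targets rose in 14 of 31 and fell in 8 (adjusted p = 0.399, adjusted p = 0.62 with an estimated correlation), and DDIT4 fell by 2.97 on the log2 scale. Host genes of snoRNAs rose in 6 of 12 and fell in 2, or 7 and 2 adjusted over the list alone (adjusted p = 0.185, adjusted p = 0.518 with an estimated correlation), led by SNHG7, whose reads cannot be told from an overlapping antisense gene without strand. Among the 35 gene lists tested in this comparison, where no second count is given, the counts adjusted over the list alone were equal to those over all genes tested.

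Genes of chromosome 13, by GENCODE 29, were lower in TMEM9 KD as a set. The 180 genes of this chromosome with a mean of at least 5 CPM had a median log2 fold change of -0.59 (95% bootstrap interval -0.66 to -0.54), and 91.1% of them were lower. The genes GJB2, SHISA2, LCP1, DNAJC3 and RPL21 named above lie on this chromosome. Chromosome 4 had a median of 0.26 and chromosome 16 of 0.20, against -0.18 for chromosome 8 and -0.11 for chromosome 7. Medians of windows of 50 consecutive genes were uneven on most of these chromosomes. They ran from 0.18 to -0.84 on chromosome 7, the latter in the window from CASP2 to UBE3C, where 88% of genes were lower. They ran from 0.02 to -0.36 on chromosome 8, from -0.0175 to 0.49 on chromosome 16 and from 0.11 to 0.43 on chromosome 4, against -0.57 to -0.65 in the 3 windows of chromosome 13. Windows on other chromosomes were also low, at -0.413 from CWF19L2 to DDX6 on chromosome 11 (82% of genes lower) and -0.39 from SCO1 to DHRS7B on chromosome 17 (86% lower). The genes named above were not checked against these windows. Against 10000 random gene sets of the same size, the medians of chromosomes 4, 7, 8, 13 and 16 each had a permutation p of 1e-04. This is the smallest p such sets can give, or 0.00044 adjusted over the 22 autosomes. In all, 15 of the 22 autosomes passed the adjusted threshold. This measure was chosen after the data were seen.

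**Figure D3:**
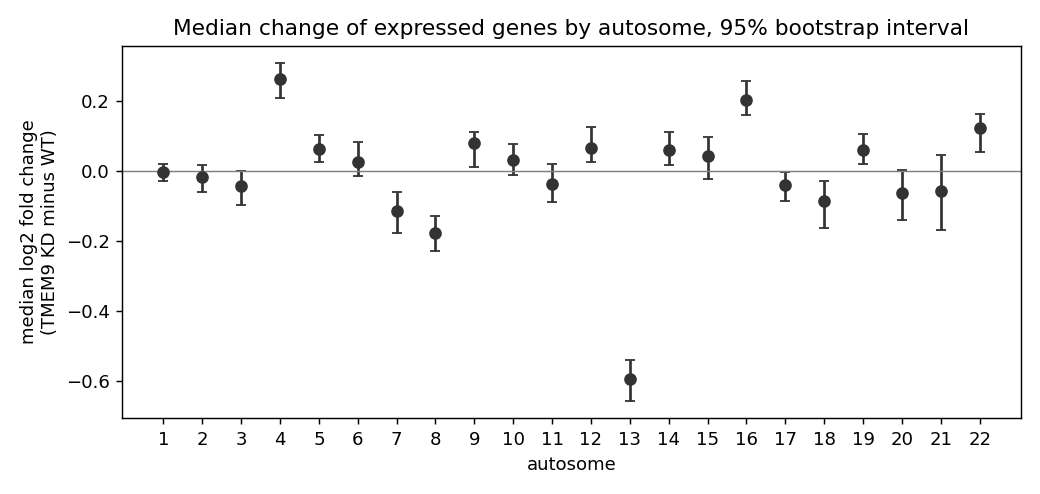
Points give the median log2 fold change of TMEM9 KD against WT over genes with a mean of at least 5 CPM on each autosome, with the 95% bootstrap interval over genes. Chromosome 13 lies at -0.59, below every other autosome.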

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

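Removal of the GC and length trend and of chromosome medians, the 2-fold counts and the chromosome 13 median were chosen after seeing the data. TMEM9 stayed lower and past the threshold in every alternative, from -4.67 without TMEM9_KD replicate 2 to -4.14 without TMEM9_KD replicate 1. Genes higher and lower ran from 3172 to 4173 and from 3450 to 4405 with a library left out. Tested against 1.5-fold, 1111 genes were higher and 1692 lower, as a larger change is asked for. This ended the calls of TCIRG1 (adjusted p = 0.214), ATP6V0A2 (0.66), CLCN4 (0.379), CLCN7 and CLCN3 (1 each), CDC20 (0.0673), DERL2 (0.45) and MT-CO2 (0.286), among others. With only genes of at least 5 CPM on average, 387 were higher and 713 lower by at least 2-fold, with fewer genes tested. DESeq2 called 3310 and 3640, and library size alone 5030 and 3730. With an estimated correlation 0 lists were higher and 0 lower, in a test with little power on 2 residual degrees of freedom. With fry, which does not compare a list with other genes, 8 were higher and 19 lower. Among the latter were v-ATPase subunits (adjusted p = 0.00259) and autophagy genes (0.021).

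With the replicate block, 4171 genes were higher and 4266 lower, the iron list was not called (adjusted p = 0.0588) and the leukocyte list was (0.0465). Leukocyte markers were also called with library size only (0.0398), DESeq2 (3.4e-05), voom (0.00883), against 1.5-fold (1.32e-05), and without TMEM9_KD replicate 1 (0.0315) or 2 (0.0302), and reached 0.05 with the GC and length trend removed. Heat shock genes were called with library size only (0.0398), DESeq2 (0.0482), voom (0.0196), chromosome medians removed (0.0333) and without TMEM9_KD replicate 2 (0.0302), and also reached 0.05 with the GC and length trend removed. G2/M genes were called with library size only (0.0398), voom (0.0338) and without TMEM9_KD replicate 2 (0.0285), and HER2 and HER3 genes under DESeq2 (0.0381) and voom (0.0446). DESeq2 also called Wnt targets (0.0482) and androgen receptor genes (0.0296). The iron list was not called against 1.5-fold (0.0728) or with at least 5 CPM (0.0765). Libraries with the same number share only the number, with a correlation of deviations of 0.000474 over 2 pairs.

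Chromosome 13 had a median of -0.000138 with chromosome medians removed, by construction. The test direction turned, with medians in brackets, for fatty acid synthesis under fry (0.16), DESeq2 (0.15), 1.5-fold (0.16), with chromosome medians removed (0.0846) and without TMEM9_KD replicate 1 (0.07, range 0.0593 to 0.22 with a library left out). It also turned for photoreceptor genes without a filter (1.05), apoptosis under DESeq2 (-0.15), luminal markers without TMEM9_KD replicate 2 (0.148, range to 0.228 without WT replicate 2), and autophagy (-0.10), ribosomal proteins (-0.0734) and oxidative phosphorylation (-0.049) at 1.5-fold. With chromosome medians removed it turned for epithelial-mesenchymal transition (-0.10) and for CLCN3 (-0.0377). The cause was not tested. With a library left out, medians ran from -0.105 to -0.0388 for ribosomal proteins, -0.0716 to -0.00861 for oxidative phosphorylation, -0.147 to -0.0947 for autophagy, -0.206 to -0.0848 for apoptosis, -0.719 to -0.216 for photoreceptor genes and -0.334 to -0.165 for epithelial-mesenchymal transition. With library size only, the medians were 0.000617 for ribosomal proteins and 0.0252 for oxidative phosphorylation, though the test direction stayed lower. Depth limits genes near 0, for which bounds or counting intervals are given.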

Other observations

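The tests here were chosen after the results were seen, except that of chromosome 13 genes by expression level. Its outcome was not known when its bounds were set, but was nearly settled by the median of the whole chromosome. Gene families outside the fixed lists were picked after their values were seen. Collagen genes fell in 17 of 26 and rose in 5 (median log2 fold change -1.05; camera adjusted p = 0.000345, adjusted p = 0.298 with an estimated correlation). COL14A1 fell from 53.5 ± 0.512 to 2.85 ± 0.38 CPM and COL17A1, a hemidesmosome collagen, from 88.3 ± 0.726 to 7.57 ± 1.37 CPM (SD, n = 2 per group). Semaphorins and plexins, ligands and receptors of axon guidance, fell in 19 of 26 and rose in 4 (adjusted p = 0.000433, adjusted p = 0.177 with an estimated correlation), with PLXND1 falling from 88.1 ± 1.79 to 12.3 ± 1.12 CPM and SEMA7A rising from 3.66 ± 0.217 to 30.1 ± 1.19 CPM. Genes whose symbol starts with IL and a digit, mostly interleukins and their receptors but also the amino acid oxidase gene IL4I1, fell in 25 of 42 and rose in 6 (adjusted p = 0.000433, adjusted p = 0.177 with an estimated correlation), and IL33 fell from 44.3 ± 0.689 to 0.554 ± 0.351 CPM.

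All 5 tested HLA class I genes fell (camera adjusted p = 0.00583, adjusted p = 0.297 with an estimated correlation), with HLA-B going from 277.5 ± 16.4 to 137.1 ± 7.09 CPM; these genes share sequence. Clade B serpins fell in 5 of 6 and rose in 1 (adjusted p = 0.00338, adjusted p = 0.177 with an estimated correlation), with SERPINB5 falling from 46.8 ± 1.74 to 1.03 ± 0.246 CPM. Mitochondrial ribosomal protein genes rose in 40 of 75 and fell in 5 (median 0.23; adjusted p = 0.00033, adjusted p = 0.177 with an estimated correlation), and MRPL1 rose from 25.4 ± 1.76 to 43.6 ± 4.02 CPM. Zinc finger genes rose in 136 of 420 and fell in 59 (median 0.15; adjusted p = 0.0132, adjusted p = 0.177 with an estimated correlation). MAGE genes rose in 6 of 14 and fell in 4 (adjusted p = 0.676, adjusted p = 0.788 with an estimated correlation). The medians of these families kept their sign under 3 other scalings. The 20 expressed genes nearest to TMEM9 in GENCODE 29 order had a median log2 fold change of -0.09, from -4.38 for INAVA to 0.49 for DDX59.

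Genes of chromosome 13 were lower in TMEM9 KD, with shifts of -0.56 and -0.65 in the 2 knockdown libraries and a difference of 0.01 between the WT libraries. A chance set of independent genes is argued against, as 10000 random sets gave a permutation p of 1e-04, the smallest they can give. The chromosome was picked for its median, and 15 of the 22 autosomes passed this test after adjustment. Neighbouring genes were not independent, as medians of windows of 50 genes had an SD of 0.174, against at most 0.0882 in 1000 shuffles. A trend on GC content and length is argued against, since its removal left a median of -0.55. A hypothesis is a copy number difference between the cultures. It asks for a shift at every expression level. Among the chromosome's genes, split by mean CPM into 3 sets of 60, the medians were -0.66, -0.58 and -0.58 (highest -0.576). With 91.1% of these genes lower, that outcome was nearly settled beforehand, and other causes that shift the whole chromosome would give it too. The split thus does not single out copy number. An effect of TMEM9 itself was not tested and stays open, and no DNA data were used here.

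Levels of several markers stood apart from what is known of MDA-MB-453, a line with luminal and apocrine features. EPCAM had a mean of 0.371 CPM over the 4 libraries and PIP, an apocrine secretory gene, no counts, while VIM had 1350 ± 9.49 CPM and FN1 4900 ± 60 CPM in WT (SD, n = 2). Fibroblasts in the cultures are argued against, as DCN and LUM reached at most 3.08 CPM in a group, and COL1A2 was at 0.746 ± 0.204 CPM in WT beside 824 ± 11.9 CPM of COL1A1. Another line or a diverged stock cannot be told apart from the named line, since no profile of it measured in the same way was used here. No biological explanation was tested.

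Of the genes tested, 57.7% were past the threshold. Scaling is argued against as the whole cause, as 3 other scalings called at least 8543 genes and kept at least 8013 of the 8618 calls. So are shifts of whole chromosomes, since the fit with their medians removed called 8443 genes and kept 7830 of those calls, with 18 in the opposite direction; shifts of smaller regions were not removed and stay open. Small changes made visible by close replicates are argued against only for the 2803 calls that passed against a 1.5-fold change. For the rest of the 8618 calls such changes stay open. The median absolute log2 fold change of the called genes was 0.605. Different cultures or clones cannot be told apart from an effect of TMEM9, as 26 genes at 5 CPM or more in a group had at most 3 counts over the other, and no second knockdown or rescue is among the libraries. The biological explanation, loss of TMEM9, stays open.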
